A study of Mus musculus with 10 samples.

How the data were processed

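RNA was sequenced from islet cells of adult mice carrying an mCherry reporter under the mouse Ins1 promoter, which marks beta cells, and a floxed YFP reporter switched on by Cre under the Sst or the Gcg promoter, which marks delta or alpha cells. Per the labels' protocols, islets of 10 to 12 animals were pooled by sex, cultured overnight at 5.5 mM glucose, dissociated and sorted by FACS, and beta cells were collected from the same islets as delta or alpha cells. RNA was extracted with Trizol, and libraries were made with the TruSeq RNA kit, version 2, which does not mark the strand. The labels do not say which libraries share islets, nor that each library is a separate pool, so p-values measure only the spread between these libraries, which may be technical in part.

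The authors deposited 1 table of RPKM values (reads per kilobase of gene, scaled to the library total) with 19213 gene entries and a column for each of the 10 libraries. Per the submitters' processing notes, STAR 2.4, featureCounts and edgeR 3.12.0 were used with the genome build GRCm38.p3. The gene annotation, the treatment of reads that fit several genes and any scaling factor are not given in the sources used here. Genes are named by the symbols in the table, 27 of which read as dates after a spreadsheet conversion and 2 of which are repeated. Gene coordinates are 1-based and come from the GENCODE annotation of GRCm38, matched by symbol, and all genes printed with coordinates other than Xist are protein coding there.

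The low values of the table are whole multiples of what 1 read is worth for a gene. From these steps the total of each library was recovered to within 0.039 of a whole number. Gene lengths were set so that values come out whole, so the 100% of values whole within 0.05 read do not check the totals. The recovered reads of each library added up to 100% of its total after rounding. The totals were 20209291 and 18570481 reads for delta replicates 1 and 2, 26223644, 24431004, 17755859, 23236294 and 26684086 for beta replicates 1 to 5, and 16688097, 16880700 and 17441439 for alpha replicates 1 to 3. RPKM are a share of the library, so abundant transcripts lower the rest. The reads of 7 hormone genes (Ins1, Ins2, Gcg, Sst, Ppy, Pyy and Iapp) took 9.8% and 10.6% of delta libraries, 17.6% to 31.8% of beta libraries and 27.5% to 30.9% of alpha libraries.

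Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, in 1 fit of all 10 libraries with cell type and sex as terms. Fold changes are on that scale, which understates the change of genes with low values. Genes with an RPKM of at least 1 in at least 2 libraries, 12700 in number, were tested. The fit has 6 residual degrees of freedom and a median of 3.16 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a gene is called at an adjusted p under 0.05. A gene counts as enriched in a cell type when it is called higher there than in each of the other types with a log2 fold change of at least 1 in both contrasts. The interaction of cell type and sex was tested in alpha and beta libraries only, since delta cells have 1 library per sex. Alpha cells have 1 female library, so this test is weak as well. The pair of comparisons with beta cells share their beta libraries, so their overlap was set beside 20 simulations of unchanged libraries and 20 splits of the beta libraries. Chi-square values per gene between libraries of 1 type were 14.7 to 229, so no library was taken as a repeat of another.

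The samples, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The 27 lists cover markers of delta, beta and alpha cells, of pancreatic polypeptide and epsilon cells, and of acinar, ductal, endothelial, stellate and mesenchymal, immune and Schwann cells, islet transcription factors, hormone and neurotransmitter receptors, hormones and neuropeptides, glucose metabolism, potassium channels, other excitability channels, exocytosis, prohormone processing, GABA and glutamate signalling, neurite genes, beta cell disallowed genes, the unfolded protein response, immediate early and heat shock genes, cell cycle genes, sex-linked genes, ribosomal proteins and oxidative phosphorylation. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists within a comparison. Of the camera calls named, none passed with an estimated correlation.

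Named genes are the 7 hormone genes, the 5 largest called differences in each direction whose libraries do not overlap, up to 3 called and 2 uncalled members of each list with at least 3 called members, the 8 called genes with the smallest adjusted p for sex (6 were called), and the 5 leading genes of each enriched set. Members of the receptor, transcription factor and marker lists could be named where values in all 3 cell types are given. Genes named outside this rule, namely C1qa, Prss2, Snord118, Hhatl, Sorcs2, Gfra1, Gpx3, Malat1, Rn45s, Ctrb1, Nts, Ankrd34c, Lyz2 and Tyrobp, were chosen after their values were seen.

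The fit was tested on simulated data with 12700 genes of which 200 were changed, 100 of them by 2-fold and 100 by 4-fold. It recovered 89% and 96% of these for delta against beta cells, 86% and 98% for alpha against beta cells, 77% and 100% for delta against alpha cells, and 97% and 99% for sex, and called 10, 7, 8 and 8 unchanged genes. The changed genes were drawn from those with a mean log2(RPKM + 1) above 2, and were changed on that scale. Recovery for genes with lower values was not tested. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean RPKM of at least 3, median-ratio scaling, quantile normalization, no trend, no sex term, only the 2 cell types compared, a block for libraries with neighbouring numbers in their titles, and each replicate left out in turn. Where this leaves delta cells with 1 library, that library is assumed to vary like the other groups. Chosen after seeing the data were voom (limma) on recovered reads, the removal of an alpha share from delta libraries and the removal of hormone reads from the totals. Plots were drawn with matplotlib 3.10.9. All deposited columns were used.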

Results

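Transcripts were measured by RNA sequencing in endocrine cells sorted from the islets of adult mice. Delta cells, which secrete somatostatin, gave 2 libraries, beta cells, which secrete insulin, gave 5, and alpha cells, which secrete glucagon, gave 3. Each cell type was sampled in both sexes, with 1 female and 1 male delta library, 3 female and 2 male beta libraries, and 1 female and 2 male alpha libraries. The design asks which genes set each endocrine cell type apart, and in particular which hormone receptors delta cells transcribe. Library totals recovered from the RPKM values lay between 16688097 and 26684086 reads, so that 1 RPKM stood for 16.7 to 26.7 reads per kb of gene. Of the genes listed, 12700 were tested. Over the tested genes the Spearman correlation between libraries of 1 cell type was 0.959 to 0.991, and no pair of libraries from different cell types exceeded 0.908.

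The hormone transcripts separated the sorts. Sst, which encodes somatostatin (chromosome 16, 23889573 to 23890958), averaged 56580 ± 5927 RPKM (SD, n = 2) in delta, 422 ± 324 (n = 5) in beta and 1829 ± 979 (n = 3) in alpha libraries. Ins1 (chromosome 19, 52264297 to 52265476) and Ins2, the insulin genes of the mouse, averaged 46780 ± 13360 and 249600 ± 69780 RPKM in beta libraries. In delta libraries they averaged 479 ± 140 and 2561 ± 619 RPKM, and in alpha libraries 324 ± 31.9 and 1878 ± 230 RPKM. Gcg, which encodes proglucagon (chromosome 2, 62474530 to 62483650), averaged 255200 ± 14950 RPKM in alpha, 22240 ± 1399 in delta and 1474 ± 866 in beta libraries. The Gcg level of the delta libraries was thus 8.72% of the alpha mean, against 0.578% in the beta libraries. In the alpha libraries Sst stood at 3.23% of the delta mean, and Ins2 in the delta libraries at 1.03% of the beta mean. How reads shared by the near-identical Ins1 and Ins2 were assigned is not given in the sources used here, so the division between them is uncertain, as it is for the related pair Ppy and Pyy.

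**Figure D1:**
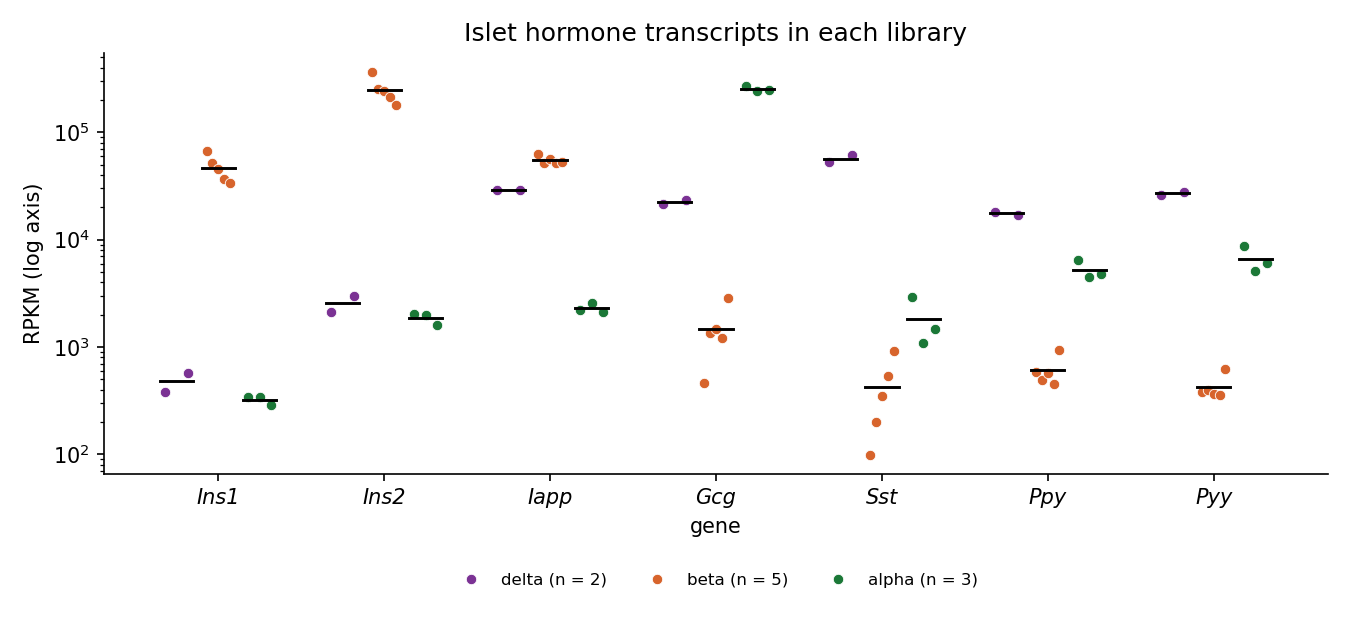
RPKM (log axis) of 7 islet hormone genes in each of the 10 libraries, with delta, beta and alpha libraries in separate colours and a bar at each group mean. Sst averages 56580 RPKM in delta libraries, Ins2 249600 in beta libraries and Gcg 255200 in alpha libraries, while Ppy and Pyy are highest in delta libraries.

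Among the genes with the largest differences between delta and beta cells were hormones, enzymes and transcription factors. Besides Sst (log2 fold change 7.51, SE 0.70, adjusted p = 3.06e-05 by limma, as for all adjusted p-values of single genes here), Hhex had one of the largest differences. Hhex encodes a homeobox factor needed for delta cells (chromosome 19, 37434810 to 37440731) and averaged 193 ± 0.195 RPKM in delta against 1.19 ± 0.885 in beta libraries (log2 fold change 6.58, SE 0.36, adjusted p = 8.54e-07). Rbp4, the plasma retinol carrier, averaged 1875 ± 124 against 21.8 ± 12 RPKM (6.55, SE 0.42, adjusted p = 2.42e-06). Arg1, the urea cycle arginase, averaged 264 ± 28.1 against 2.34 ± 1.18 RPKM (6.37, SE 0.30, adjusted p = 3.29e-07). Lower in delta cells were, besides both insulin genes (each log2 fold change -6.61), G6pc2, the glucose-6-phosphatase of islets (-6.14, SE 0.11), Ucn3, the peptide urocortin 3 (-6.08, SE 0.27), and the insulin gene activator Mafa (-5.79, SE 0.24), each at an adjusted p of at most 2.29e-07.

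The peptides Pyy and Ppy, neighbours on chromosome 11 (102106676 to 102107832 and 102099930 to 102101319), were abundant in the delta libraries. Which cells of the sort carried them was not tested. Pyy averaged 26930 ± 1241 RPKM in delta, 426 ± 112 in beta and 6607 ± 1880 in alpha libraries, a delta to beta log2 fold change of 6.02 (SE 0.26, adjusted p = 2.14e-07). Ppy averaged 17550 ± 792, 608 ± 191 and 5268 ± 1104 RPKM (4.89, SE 0.27, adjusted p = 9.8e-07). With Sertm1 they made 3 of the 4 tested markers of pancreatic polypeptide and epsilon cells higher in delta than in beta cells, also when adjusted over the list alone (camera adjusted p = 0.0152, adjusted p = 0.497 with an estimated correlation). Iapp, the amyloid peptide released with insulin, averaged 28950 ± 209 RPKM in delta and 55440 ± 4709 in beta libraries. Its log2 fold change of -0.95 (SE 0.19, adjusted p = 0.00279) did not pass without the filter on low values (adjusted p = 0.551) or without delta replicate 1 (adjusted p = 0.0526), and turned to 0.096 under quantile normalization.

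Of 11 tested delta cell markers, 10 were higher in delta than in beta cells and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00015, adjusted p = 0.497 with an estimated correlation). The list contains Ghsr, whose transcription in delta cells the study reported from these libraries, so it is no independent evidence of its own direction. Of 17 beta cell markers, 15 were lower and 0 higher in delta cells, and 16 were lower adjusted over the list alone (camera adjusted p = 2.21e-20, adjusted p = 0.055 with an estimated correlation). Slc2a2, the glucose transporter of mouse beta cells, had a log2 fold change of -4.74. Pdx1, a factor of pancreas and beta cell development, stayed at 74.1 ± 5.85 RPKM in delta against 96.9 ± 14.5 in beta libraries (adjusted p = 0.115). Median-ratio scaling (adjusted p = 0.0344) and leaving out alpha replicate 1 (adjusted p = 0.0466) each brought Pdx1 past the threshold, as lower in delta cells, as did leaving out hormone reads (adjusted p = 0.0306), an alternative chosen after seeing the data.

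Alpha cell markers were also higher in delta than in beta cells, 12 of 14 with 0 lower, likewise adjusted over the list alone (camera adjusted p = 0.00334, adjusted p = 0.497 with an estimated correlation). Gcg led them with a log2 fold change of 4.19 (SE 0.50, adjusted p = 0.000138), followed by the transcription factor Etv1 (42.5 RPKM in delta, 3.81 in beta, 46.9 in alpha libraries) and by Gc, the vitamin D binding protein (2.60, SE 0.27, adjusted p = 6.6e-05). Under median-ratio scaling 10 were higher, while Slc7a2 and Sv2b were lower. After subtraction of an alpha share set by Gcg, an alternative chosen after seeing the data, 6 of the 14 stayed higher. Among the 36 genes at 10 RPKM or more in alpha libraries and at most 3% of that in beta libraries, the level in delta libraries was 8.72% of the alpha mean for Gcg, with a median of 15.9% and a range up to 228%.

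**Figure D2:**
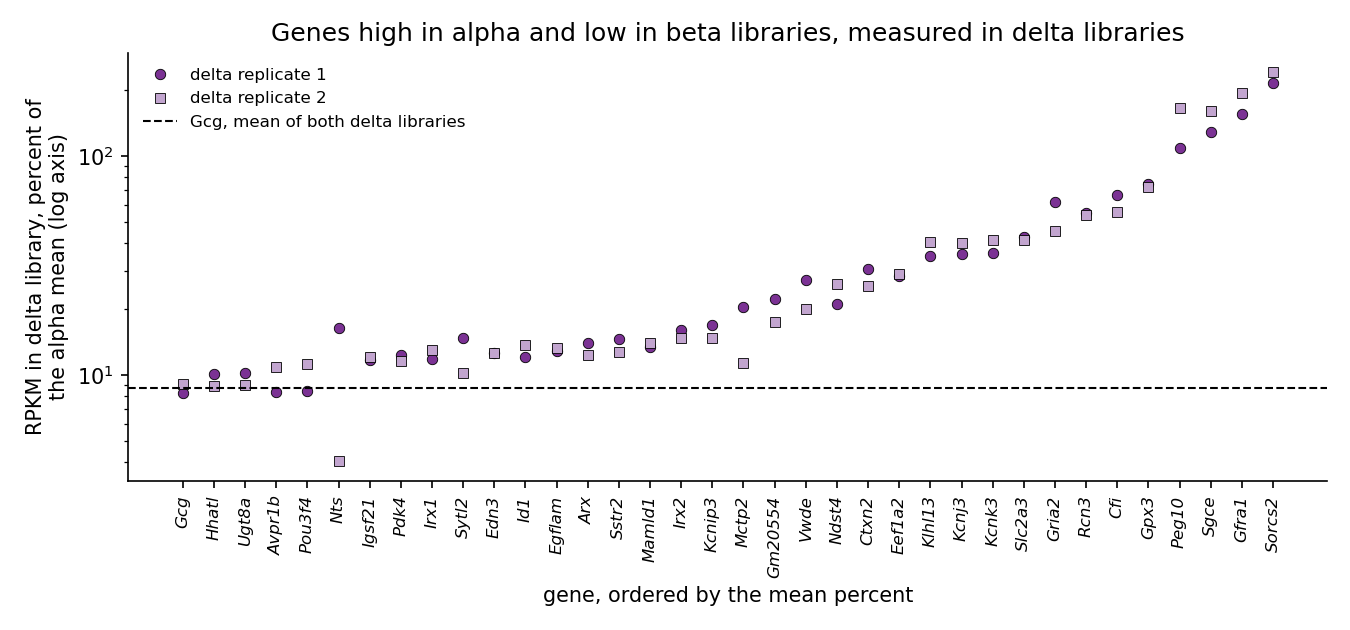
RPKM in each of the 2 delta libraries as a percentage of the mean of the 3 alpha libraries (log axis) for 36 genes high in alpha and low in beta libraries, ordered by the mean of both delta libraries, with a dashed line at the Gcg share. Gcg lies at 8.72%, the lowest other gene (Hhatl) at 9.52% and the highest (Sorcs2) at 228%.

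Of 32 islet transcription factors, 20 were higher and 4 lower in delta than in beta cells, and 23 and 4 adjusted over the list alone (camera adjusted p = 0.0465, adjusted p = 0.831 with an estimated correlation). Neurog3, the factor that starts endocrine differentiation in the embryo (chromosome 10, 62133090 to 62134763), averaged 59.2 ± 0.581 RPKM in delta against 0.452 ± 0.176 in beta libraries (log2 fold change 5.37, SE 0.20, adjusted p = 9.37e-08). The zinc finger factor Insm1 stood at 96.5 and 103 RPKM and was not called. The 22 hormones and neuropeptides had 6 higher and 8 lower members, the same counts adjusted over the list alone (camera adjusted p = 0.0139, adjusted p = 0.303 with an estimated correlation).

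Genes of glucose uptake and metabolism were lower in delta than in beta cells in 10 of 26 cases and higher in 4, with the same counts adjusted over the list alone, and in 14 and 4 under median-ratio scaling (camera adjusted p = 0.00138, adjusted p = 0.476 with an estimated correlation). G6pc2 and Slc2a2 were among the lower genes, while Pdk4, a kinase that inhibits pyruvate dehydrogenase, was higher in the delta libraries (3.14, SE 0.21, adjusted p = 3.3e-06). With the alpha share set by Gcg removed, the Pdk4 change was 1.47 (adjusted p = 0.00113). Of 74 genes of oxidative phosphorylation, 33 were lower and 1 higher, again also adjusted over the list alone, and 48 and 1 under median-ratio scaling (camera adjusted p = 1.77e-11, adjusted p = 0.489 with an estimated correlation). Cox6a2, a cytochrome oxidase subunit isoform of muscle, had a log2 fold change of -4.65, the complex III subunit Uqcrq of -1.39 and Cox5a of -1.01. Without delta replicate 1, 12 of the 74 were lower. Of 17 genes known to be kept silent in beta cells, often called disallowed, 10 were higher and 2 lower in delta cells, also adjusted over the list alone, but 6 were higher without delta replicate 1. A gene silent in beta cells passes the filter only through other libraries, so the filter favours higher members of the disallowed list. Ribosomal protein genes had 3 higher and 7 lower of 76, 0 of each adjusted over the list alone, and 1 and 21 under median-ratio scaling. Camera called the ribosomal list as lower (adjusted p = 0.000119, adjusted p = 0.729 with an estimated correlation).

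Channel and secretion genes differed in both directions. Of 22 potassium channel genes, 11 were higher and 6 lower in delta cells, also adjusted over the list alone. Kcnk3, a tandem-pore channel, Kcnj3, an inward rectifier, and the A-type channel Kcnd2 had log2 fold changes of 3.13, 2.30 and 2.19. Of 26 sodium, calcium and other excitability channels, 15 were higher and 4 lower, and 16 and 4 adjusted over the list alone, but 9 were higher without delta replicate 1. Cacna1h, a T-type calcium channel, averaged 25.1 ± 2.06 RPKM in delta against 0.182 ± 0.0797 in beta libraries (4.47, SE 0.12). The calcium channel subunit Cacna2d2 had a log2 fold change of 4.35 and the sodium channel subunit Scn3b of 3.71. Of 30 granule exocytosis genes, 13 were higher and 7 lower, also adjusted over the list alone, and 8 and 10 under median-ratio scaling. Without delta replicate 1, 7 were higher. Sytl4, which tethers granules, had a log2 fold change of -5.61, the calcium sensor Syt1 of 4.28 and Rab3b, a vesicle GTPase, of 1.69. Of 16 genes of prohormone processing, 8 were higher and 5 lower, 9 and 5 adjusted over the list alone, and 2 and 5 under median-ratio scaling. In the fits without delta replicate 1 and without delta replicate 2, 3 were higher. The convertase Pcsk1 was lower (-3.02), and Gnas, the stimulatory G protein locus with an antisense partner that unstranded libraries do not resolve, was higher (2.05).

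Of 12 genes of GABA and glutamate signalling, 7 were higher and 3 lower in delta cells, also adjusted over the list alone. Gad1, which makes GABA (-4.52), and the GABA receptor subunit Gabbr2 (-4.08) were lower, while the glutamate receptor subunit Gria2 was higher (2.99). Neurite and axon genes were higher in 15 of 23 cases and lower in 3, also adjusted over the list alone (camera adjusted p = 0.0152, adjusted p = 0.802 with an estimated correlation). Gap43, a growth cone protein, averaged 71.35 ± 4.52 RPKM in delta against 0.36 ± 0.16 in beta libraries (5.76, SE 0.23, adjusted p = 1.66e-07). The phosphatase Ptprz1 had a log2 fold change of 5.21 and the ephrin Efnb3 of 5.04. Of 21 immediate early and heat shock genes, 13 were higher and 1 lower, and 13 and 2 adjusted over the list alone, with log2 fold changes of 3.19 for Egr1, 2.42 for Jun and 2.41 for Fos. Of 27 genes of the unfolded protein response and ER folding, 13 were higher and 7 lower, 15 and 7 adjusted over the list alone, and 8 of each under median-ratio scaling. The fit without delta replicate 1 had 6 higher. The oxidase Ero1lb (-3.98) and the stress pseudokinase Trib3 (-1.95) were lower, while the stress factor Atf3 was higher (1.62) but not called without delta replicate 1 (adjusted p = 0.0605). Camera called none of the channel, exocytosis, prohormone, GABA, immediate early or ER folding lists in this comparison.

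Markers of immune cells were lower in delta than in beta cells in 10 of 11 cases, also adjusted over the list alone (camera adjusted p = 1.14e-07, adjusted p = 0.476 with an estimated correlation). Cd74, the invariant chain of MHC class II, averaged 50.6 ± 19.9 RPKM in beta, 3.02 ± 0.258 in delta and 2.10 ± 0.374 in alpha libraries, and H2-Aa, an MHC class II chain, 23.6 ± 8.64, 0.658 ± 0.21 and 1.04 ± 0.176 RPKM. C1qa, a complement component, went the other way, with 65.6 ± 11.2 RPKM in delta against 28.9 ± 7.68 in beta libraries (adjusted p = 0.00447, and 0.0779 without delta replicate 2). Many transcripts of acinar cells, the exocrine cells around islets, varied widely between libraries of the same type. Prss2, a trypsinogen, stood at 21.1 to 1200 RPKM across beta libraries and at 53.8 and 98.1 in delta libraries. Of 17 tested acinar markers 0 were called between delta and beta cells by limma, with the same count adjusted over the list alone. Camera called the list as lower in delta cells (adjusted p = 0.0152, adjusted p = 0.878 with an estimated correlation).

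In all, 4750 of 12700 genes were higher and 1692 lower in delta than in beta cells at an adjusted p under 0.05, and 1550 and 489 of these by at least 2-fold. Higher genes made up 73.7% of the calls as deposited and 55.4% (3448 higher, 2780 lower) after median-ratio scaling. That scaling moves all genes of a library alike, and so evens the split by its construction, with the median log2 fold change of all genes going from 0.253 to 0.053. Without delta replicate 1 the counts were 2335 and 938.

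Alpha cells differed from beta cells most in Gcg, with a log2 fold change of 7.79 (SE 0.44, adjusted p = 1.09e-06), and in both insulin genes (-7.18 for Ins1 and -7.08 for Ins2). Pdk4 averaged 113 ± 12.8 RPKM in alpha against 0.692 ± 0.403 in beta libraries (6.12, SE 0.19, adjusted p = 3.36e-08), and Eef1a2, a translation elongation factor of neurons and muscle, 154 ± 18.8 against 1.99 ± 0.832 (5.79, SE 0.20, adjusted p = 5.02e-08). Edn3, the peptide endothelin 3, and the homeobox genes Irx1 and Irx2 had log2 fold changes of 5.55, 5.35 and 5.005. Lower in alpha cells were the serine protease gene Prss53 (-6.48, SE 0.26), Ucn3 (-6.37, SE 0.24) and B830017H08Rik (-6.14, SE 0.09). Iapp was lower (-4.63). Sst, Ppy and Pyy were higher in alpha than in beta libraries by 2.54, 3.13 and 3.98. Their adjusted p-values were 0.00805, 7.59e-06 and 1.24e-06. Sst in the alpha libraries stood at 3.23% of its delta mean, and which cells of the alpha sort carried these transcripts was not tested.

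Alpha cell markers were higher in alpha than in beta cells in 13 of 14 cases, and lower in 1, with the same counts adjusted over the list alone (camera adjusted p = 3.82e-10, adjusted p = 0.138 with an estimated correlation). The lower gene was Dpp4, the peptidase that inactivates GLP-1 (10.1 RPKM in alpha, 18.9 in beta and 28.9 in delta libraries). Beta cell markers were lower in 16 of 17 cases, also adjusted over the list alone (camera adjusted p = 7.07e-11, adjusted p = 0.138 with an estimated correlation), among them Mafa (-5.98) and the glucose genes Slc2a2 (-5.22) and G6pc2 (-5.18). The exception was the zinc transporter gene Slc30a8, at 398 RPKM in alpha, 185 in beta and 43.8 in delta libraries. Of 11 delta cell markers, 6 were higher and 2 lower, and 7 and 2 adjusted over the list alone. Among them were Rbp4 (4.15) and the Wnt antagonist Frzb (-4.28). Which cells of the alpha sort carried the higher ones was not tested. All 4 markers of pancreatic polypeptide and epsilon cells were higher in alpha cells, also adjusted over the list alone (camera adjusted p = 0.00125, adjusted p = 0.472 with an estimated correlation).

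Genes of the unfolded protein response and ER folding were lower in alpha than in beta cells in 22 of 27 cases with 0 higher, and in 24 adjusted over the list alone (camera adjusted p = 4.11e-07, adjusted p = 0.413 with an estimated correlation). Trib3 had a log2 fold change of -4.62 (SE 0.20), Ero1lb of -3.22 (SE 0.13) and Ddit3, the stress factor CHOP, of -2.59 (SE 0.18), each at an adjusted p of at most 3.88e-06. Of 74 oxidative phosphorylation genes, 44 were lower and 2 higher, 45 and 2 adjusted over the list alone (camera adjusted p = 0.000183, adjusted p = 0.851 with an estimated correlation), and 24 were lower under median-ratio scaling and 26 without alpha replicate 3. Cox6a2 (-4.65) and Uqcrq (-1.55) were among the lower genes. Of the 17 disallowed genes 9 were higher and 3 lower in alpha cells, and 10 and 3 adjusted over the list alone. Camera gave an adjusted p = 0.0495, and an adjusted p = 0.851 with an estimated correlation. The filter on low values favoured higher members here too. Oat, an ornithine aminotransferase, Hk1, a hexokinase of high glucose affinity, and Igfbp4, which binds insulin-like growth factors, had log2 fold changes of 3.85, 3.23 and 3.20. Without alpha replicate 2, 5 of the 17 were higher.

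Of 32 islet transcription factors, 14 were higher and 8 lower in alpha than in beta cells, and of 32 hormone and neurotransmitter receptors 11 and 15. Adjusted over the list alone these counts were 14 and 8, and 12 and 15. Of 26 genes of glucose uptake and metabolism, 5 were higher and 13 lower, and 6 and 13 adjusted over the list alone. Potassium channels had 6 higher and 9 lower of 22, led by Kcnk3 (4.46), the channel partner Kcnip1 (-4.06) and Kcnj3 (3.52). Other excitability channels had 10 and 6 of 26 (11 and 6 adjusted over the list alone), led by the cation channels Trpm5 (-3.77) and Hcn4 (-1.99). Exocytosis genes had 9 higher and 12 lower of 30, with Sytl4 at -5.61 and the vesicle GTPase Rab3c at 2.96. Prohormone genes had 4 and 6 of 16, with Pcsk1 at -5.82, Gnas at 2.23 and the granin Scg2 at -1.67. Of 12 GABA and glutamate genes, 6 were higher and 5 lower, with Gad1 at -4.24, Gria2 at 3.83 and the subunit Gria3 at 3.43. Of 23 neurite genes 10 were higher and 8 lower, with the neurofilament gene Nefm at 2.79. For the potassium channel, exocytosis, prohormone, GABA and neurite lists the counts adjusted over the list alone were the same, and camera called none of the lists named in this paragraph.

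Immune cell markers were lower in alpha than in beta cells in all 11 cases, also adjusted over the list alone (camera adjusted p = 3.2e-05, adjusted p = 0.652 with an estimated correlation), with Cd74 at -4.00, H2-Aa at -3.53 and the complement gene C1qb at -2.94. Among 10 ductal markers 4 were higher and 4 lower, also adjusted over the list alone. Spp1, the secreted phosphoprotein osteopontin, averaged 1281 ± 557 RPKM in alpha against 226 ± 67.8 in beta libraries (2.38, SE 0.33, adjusted p = 0.000326). In all, 3013 genes were higher and 3851 lower in alpha than in beta cells, 913 and 984 of them by at least 2-fold. After median-ratio scaling they numbered 3894 and 3329, so that the share of higher genes went from 43.9% to 53.9%. Without alpha replicate 3 the number of higher genes was 1838.

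Delta and alpha cells came from different reporter crosses, so cross and cell type cannot be separated in their comparison. Cd24a, a glycosylated surface antigen, averaged 562 ± 7.19 RPKM in delta against 11.5 ± 3.59 in alpha libraries (log2 fold change 5.51, SE 0.34, adjusted p = 3.07e-06). It was followed by Hhex (5.45, SE 0.39), Ly6h, an anchored membrane protein of the Ly6 family (5.21, SE 0.28), Frzb (5.19, SE 0.27) and Sst (4.97, SE 0.77). Lower in delta cells were Gcg (-3.61, SE 0.54, adjusted p = 0.00079), Hamp, the iron hormone hepcidin (-3.92, SE 0.49), the mitochondrial protein gene Higd1a (-3.36, SE 0.35) and Ttr, the thyroid hormone carrier transthyretin (-3.35, SE 0.21). Lrg1, a secreted glycoprotein, was lower by its main estimate of -3.46 (SE 0.83, adjusted p = 0.00994) but not called without delta replicate 1 (adjusted p = 0.0505), delta replicate 2 (0.0813) or alpha replicate 3 (0.0579), nor by voom on recovered reads (0.0723), an alternative chosen after seeing the data.

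Iapp was higher in delta than in alpha cells by 3.68 on the log2 scale (SE 0.20, adjusted p = 1.71e-06, and 0.0577 without the filter on low values), and Ppy and Pyy by 1.76 and 2.05 (adjusted p = 0.00149 and 0.000489). Under quantile normalization Ppy stood at -0.169 and Pyy at -0.034. Ins1 and Ins2 were not called, with adjusted p-values of 0.166 and 0.278. Of 22 hormones and neuropeptides 8 were higher and 7 lower, also adjusted over the list alone. Pdyn, the dynorphin precursor, averaged 94.5 ± 27.5 RPKM in delta, 164 ± 31.1 in beta and 2.94 ± 1.51 in alpha libraries (4.64, SE 0.32, adjusted p = 6.43e-06). In the alpha to beta comparison the same list had 8 higher and 8 lower, also adjusted over the list alone.

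Of the delta cell markers 10 of 11 were higher in delta than in alpha cells, also adjusted over the list alone (camera adjusted p = 2.77e-05, adjusted p = 0.498 with an estimated correlation), with the same caution about Ghsr as above. Of the alpha cell markers 11 of 14 were lower and Dpp4 was higher, also adjusted over the list alone (camera adjusted p = 6.02e-16, adjusted p = 0.0893 with an estimated correlation). Gc averaged 229 ± 6.56 RPKM in delta against 313 ± 37.6 in alpha libraries and was not called (adjusted p = 0.358, and 0.0207 in a fit of these 2 cell types alone). Of the 17 beta cell markers 5 were higher and 4 lower in delta than in alpha cells, also adjusted over the list alone, among them Pdx1 at 74.1 against 3.84 RPKM (3.965, SE 0.20, adjusted p = 9.45e-07). Of 32 islet transcription factors 14 were higher and 7 lower, also adjusted over the list alone, with Neurog3 at 4.84.

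Genes of the unfolded protein response and ER folding were higher in delta than in alpha cells in 25 of 27 cases and lower in 1, Ero1lb, also adjusted over the list alone, and in 22 and 1 under median-ratio scaling (camera adjusted p = 1.06e-06, adjusted p = 0.345 with an estimated correlation). Trib3, the ER membrane protein gene Herpud1 and the chaperone cofactor gene Sdf2l1 had log2 fold changes of 2.68, 2.29 and 1.93, each at an adjusted p of at most 0.000577. Of 21 immediate early and heat shock genes 10 were higher and 1 lower, also adjusted over the list alone, but 6 were higher under median-ratio scaling and 3 without delta replicate 1. The nuclear receptor gene Nr4a1 had a log2 fold change of 2.82 (SE 0.35, adjusted p = 0.000236). Fosb (2.01) and Fos (1.9999) were not called without delta replicate 1, at adjusted p-values of 0.0559 and 0.133. In the alpha to beta comparison 7 of the 21 were higher and 3 lower, also adjusted over the list alone.

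Genes of glucose uptake and metabolism were lower in delta than in alpha cells in 7 of 26 cases and higher in 3, also adjusted over the list alone, and in 8 and 0 under median-ratio scaling (camera adjusted p = 0.000126, adjusted p = 0.345 with an estimated correlation). Lower were Pdk4 (-2.98), Hk1 (-2.13) and Gpd2, the mitochondrial glycerol phosphate dehydrogenase (-1.49). Disallowed genes had 5 higher and 7 lower of 17, and 6 and 7 adjusted over the list alone (camera adjusted p = 0.0343, adjusted p = 0.849 with an estimated correlation). Neurite genes were higher in 12 of 23 cases and lower in 3, 14 and 3 adjusted over the list alone (camera adjusted p = 0.0691), with Ptprz1 at 4.71, Gap43 at 4.70 and Efnb3 at 4.06. Potassium channels had 10 higher and 5 lower of 22, 11 and 5 adjusted over the list alone, with Kcnip1 at 3.93, Kcnh6 at -3.05 and the subunit Kcnmb2 at 2.21, but 6 and 5 under median-ratio scaling. Other excitability channels had 10 higher and 2 lower of 26, also adjusted over the list alone, with Cacna2d2 at 4.1978 and Cacna1h at 4.07, but 6 and 5 under median-ratio scaling, and 6 were higher without delta replicate 2. Exocytosis genes had 13 higher and 4 lower of 30, 14 and 4 adjusted over the list alone, with Syt1 at 3.23 and Rab3b at 2.86, but 8 and 5 under median-ratio scaling, and 8 were higher without delta replicate 1. Prohormone genes had 7 higher and 4 lower of 16, also adjusted over the list alone, with Pcsk1 at 2.79, the granin Chgb at 2.50 and Scg2 at 2.08, but 4 and 5 under median-ratio scaling, and 4 were higher without delta replicate 1.

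Of 12 GABA and glutamate genes 5 were higher and 4 lower in delta than in alpha cells, also adjusted over the list alone. Markers of pancreatic polypeptide and epsilon cells had 2 higher and 1 lower of 4, with Sertm1 lower, and immune markers 2 higher and 0 lower of 11 (1 and 0 under median-ratio scaling), in both cases also adjusted over the list alone. Ribosomal protein genes had 1 higher and 8 lower of 76, 0 and 1 adjusted over the list alone, and 0 and 21 under median-ratio scaling (camera adjusted p = 7.7e-09, adjusted p = 0.498 with an estimated correlation). Oxidative phosphorylation genes had 10 higher and 4 lower of 74 as deposited, 0 and 11 under median-ratio scaling, and 1 of each adjusted over the list alone (camera adjusted p = 0.0156 for lower, adjusted p = 0.854 with an estimated correlation). Without delta replicate 2, 1 of them was higher, and without alpha replicate 3, 2 were. With the alpha share set by Gcg removed, the log2 fold changes between delta and alpha cells of Ttr, Higd1a, Kcnh6 and Pdk4 were, by construction, further from 0 (-6.72, -5.32, -4.84 and -4.62).

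In all, 4076 genes were higher and 748 lower in delta than in alpha cells, 1164 and 347 of them by at least 2-fold. After median-ratio scaling they numbered 1919 and 1360, so that the share of higher genes went from 84.5% to 58.5%. Without delta replicate 1 the number of higher genes was 2181, and without delta replicate 2 the number of lower genes was 481.

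Genes higher in 1 cell type than in each of the others, by at least 2-fold in both comparisons, numbered 601 in delta, 382 in beta and 229 in alpha cells. The largest margins in delta cells belonged to Hhex, Cd24a, Ly6h, Sst and Neurog3, in beta cells to Ins1, Ins2, Ucn3, Mafa and Prss53, and in alpha cells to Hamp, Gcg, Higd1a, Ttr and Fgb. The last, a fibrinogen chain, averaged 82.8 ± 47.5 RPKM in alpha, 6.78 ± 2.52 in delta and 5.15 ± 3.67 in beta libraries. With a filter of a mean RPKM of at least 3, the delta and alpha sets held 332 and 133 genes, while the order of the delta and beta sets turned under median-ratio scaling (414 and 449) and quantile normalization (375 and 505).

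Of 32 tested receptors for hormones and neurotransmitters, 15 were higher and 13 lower in delta than in beta cells, also adjusted over the list alone. Between delta and alpha cells 16 were higher and 11 lower in delta cells, and 17 and 12 adjusted over the list alone. Ghsr, the receptor of ghrelin (chromosome 3, 27371351 to 27378010), averaged 48.4 ± 2.43 RPKM in delta, 0.263 ± 0.262 in beta and 0.842 ± 0.524 in alpha libraries (delta to beta log2 fold change 5.31, SE 0.23, adjusted p = 2.3e-07; delta to alpha 4.78, SE 0.26, adjusted p = 1.46e-06). The somatostatin receptor Sstr1 (18.3 in delta, 0.182 in beta and 1.01 RPKM in alpha libraries), the muscarinic receptor Chrm4 (22.1, 2.26 and 1.13) and Crhr2, a receptor of urocortins (5.14, 0.0296 and 0.0799), were likewise highest in delta cells. Glp1r, the GLP-1 receptor, averaged 39.9 RPKM in delta, 150.5 in beta and 2.47 in alpha libraries, the glucagon receptor Gcgr 5.62, 15.5 and 0.264, and the adrenergic receptor Adra2a 9.72, 33.4 and 0.683. In alpha cells the vasopressin receptor Avpr1b (4.09 in delta, 0.295 in beta, 42.4 in alpha libraries), Sstr2 (2.46, 0.151 and 17.99), the lipid receptor Gpr119 (4.40, 3.53 and 32.6) and the adrenergic receptor Adrb1 (0.464, 0.0256 and 4.50) were highest. The fatty acid receptors Ffar1 and Ffar4 went opposite ways between delta and beta cells, with log2 fold changes of -4.21 and 4.09, and stood at 10.9 and 23.3 RPKM in alpha libraries. Camera called this list in none of the comparisons.

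**Figure D3:**
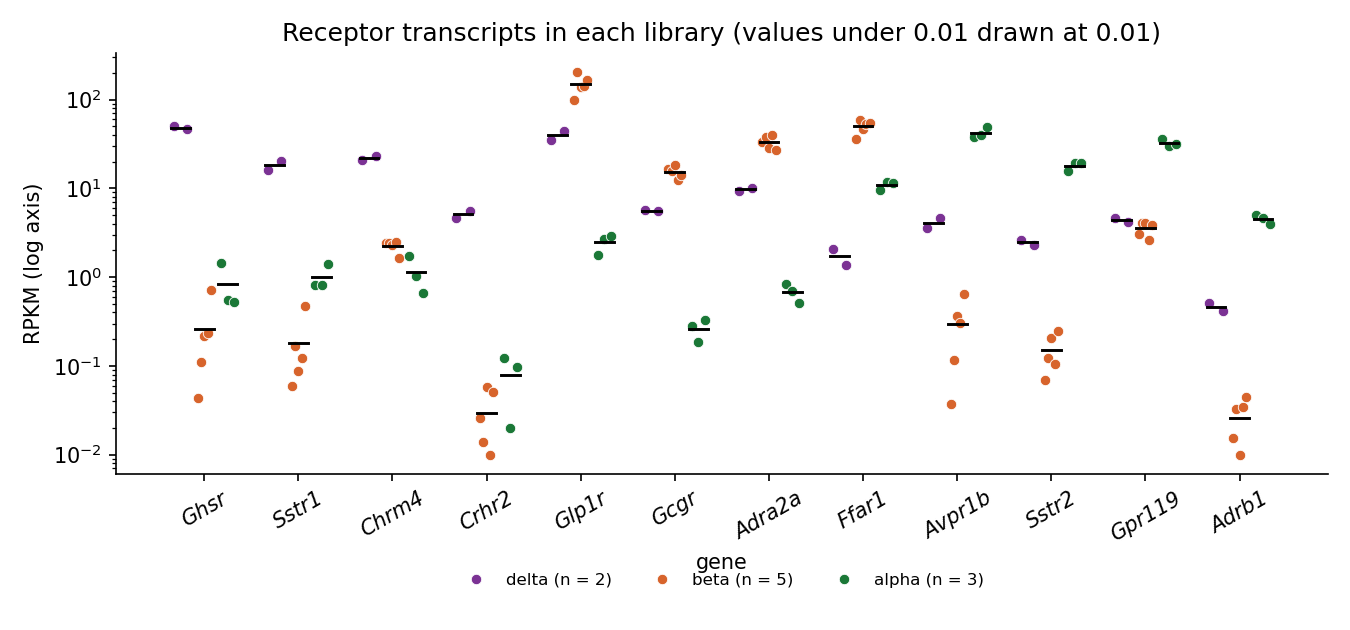
RPKM (log axis, values under 0.01 drawn at 0.01) of 12 receptor genes in each of the 10 libraries, with delta, beta and alpha libraries in separate colours and a bar at each group mean. Ghsr averages 48.4 RPKM in delta against 0.263 in beta libraries, Glp1r 150.5 RPKM in beta against 2.47 in alpha libraries, and Avpr1b 42.4 RPKM in alpha against 0.295 in beta libraries.

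Females and males differed in 6 genes, 2 higher and 4 lower in females. Xist, the RNA that silences an X chromosome (chromosome X, 103460366 to 103483254), averaged 112 ± 80.3 RPKM in female and 0.358 ± 0.17 in male libraries (n = 5 each, log2 fold change 6.22, SE 0.45, adjusted p = 0.00072), though unstranded reads do not separate it from its antisense gene. The Y-linked genes Eif2s3y, a translation factor (-4.93), Ddx3y, an RNA helicase (-3.81), and the demethylase family genes Uty (-2.85) and Kdm5d (-2.71) made up the lower genes, at adjusted p-values of at most 0.00072. The remaining gene was the microRNA gene Mir7024, at 2.26 ± 1.7 against 0.928 ± 0.964 RPKM (1.07, SE 0.11, adjusted p = 0.00769). It was not called without either delta replicate (adjusted p = 0.064 and 0.059), without beta replicate 1 (0.0534) or 3 (0.06), without alpha replicate 3 (0.0577), with a pseudocount of 0.1 (0.181), or by voom on recovered reads (0.754). Of 9 sex-linked genes 1 was higher and 4 were lower, and 5 and 4 adjusted over the list alone.

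By camera the lists of glucose metabolism (adjusted p = 0.00164), acinar markers (5.63e-06), ribosomal proteins (1.67e-11) and oxidative phosphorylation (1.2e-15) were lower and the neurite list (0.00364) higher in females, with 0 members called by limma in any of these lists. Each had an adjusted p = 0.556 with an estimated correlation. Acinar transcripts ran with sex in beta libraries in part, as Prss2 stood at 1200 and 270 RPKM in males and at 49.4, 21.1 and 560 in females. Over all genes 634 had an unadjusted p under 0.05.

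Whether the alpha to beta difference itself depended on sex was tested in the 3 alpha and 5 beta libraries. The test rests on 1 female alpha library, so an absence of calls says little. By limma 0 genes passed, 147 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0554, for the small nucleolar RNA gene Snord118. Median-ratio scaling called 1 gene, and leaving out alpha replicate 2 called 5.

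In the comparisons with beta libraries, 2310 genes were higher in both alpha and delta libraries and 1447 lower in both. Independent lists of these sizes would share 1127 and 513. With the beta libraries split between the comparisons, the median over 20 splits was 1531 higher and 1137.5 lower genes, where independent lists of the sizes called in the splits would share a median of 689 and 362. With the alpha share set by Gcg removed from the delta libraries, an alternative chosen after seeing the data, 1957 genes were higher in both and 1732 lower in both, where independent lists would share 897 and 665. The covariance of the log2 fold changes was 0.5, against 0.011 in 20 simulations of unchanged libraries against the same beta libraries. Their correlation was 0.665, against 0.329. The simulations hold no changed genes, so their correlation is that of noise alone. With the beta libraries split between the comparisons, the covariance was 0.456 to 0.505 and the correlation 0.6 to 0.655.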

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

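All tests of explanations in this part were chosen after the results were seen, and the search for libraries far from their group was set before. The 5 beta libraries were searched for a value whose gap to the nearest other library exceeded 0.71 of the whole range, and 7 of the 95 values searched had one, where chance gives about 1 in 20. Pyy stood at 626 RPKM in beta replicate 5 against 359 to 399 in the others. Chrm4, at 1.65 RPKM against 2.30 to 2.49, and Ly6h, at 0.767 RPKM against 0.139 to 0.283, stood apart in the same library. Gcg, Sst and Ppy were also highest there among the beta libraries, at 2850, 922 and 934 RPKM, without being flagged. Chrm4, higher in delta than in beta libraries like Ly6h, went the other way. The cause was not tested. In beta replicate 2, Slc2a2 was at 165 RPKM against 72.4 to 84.8, Atf3 at 3.87 against 6.79 to 7.14 and Higd1a at 0.524 against 2.22 to 3.34. Gnas was at 146 RPKM in beta replicate 1 against 168 to 178.

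Transcripts high in alpha cells were present in the delta libraries, with Gcg at 8.33% and 9.11% of the alpha mean. Transcription of Gcg alone in delta cells is argued against, because the other 35 genes high in alpha and low in beta libraries had a lower quartile of 12.6% over the mean of both delta libraries, against 8.72% for Gcg. One alpha share as the whole source is argued against as well, because 45.7% of them, 16 genes, lay above 2 Gcg shares in both delta libraries, among them Sorcs2 at 228%, Gfra1 at 175% and Gpx3 at 73.5%. Alpha cells or their RNA in the delta sort stay open, since the lowest other gene by that mean, Hhatl, stood at 9.52%, and so does transcription of many alpha genes by delta cells. The size of an alpha share is not settled. Nts stood at 4.04% in delta replicate 2. Of all 5833 genes at 10 RPKM or more in alpha libraries, whatever their beta level, 7 lay under the Gcg share. Among them were Lrg1 at 2.98%, Hamp at 4.57% and Ankrd34c at 4.80%. Lrg1 ranged from 4.38 to 31.0 RPKM between alpha libraries and Hamp from 21.9 to 60.1. Their percentages thus depend on the alpha library taken. Ankrd34c ranged from 9.27 to 16.7 RPKM.

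Immune transcripts were higher in every beta library than in every delta and alpha library for 13 of 14 listed genes, C1qa being the exception. The chance rate of 0.4% per gene assumes libraries that do not differ by cell type, so it is no yardstick here. Of the 12700 tested genes, 1447 were called lower in both delta and alpha cells than in beta cells. The immune list had already been called lower in both, so this ranking adds little to those calls. How many of all genes were higher in every beta library was not counted. Whether a lower purity of the beta sort for every other cell type is the source of the immune transcripts cannot be told. Most of the 32 listed endothelial, mesenchymal and Schwann transcripts lay near 0. None of the 32 were higher in every beta library, and of those that passed the filter on low values 0% of 8 were, against 10 of 11 immune transcripts. Immune cells or their RNA in the beta sort stay open as a candidate source, with Lyz2, a lysozyme of macrophages, at 5.48 RPKM and Tyrobp, an immune adaptor, at 4.35 RPKM in beta libraries. Transcription of these genes by beta cells stays open and untested, since sorting gate and cell type go together.

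More genes were higher than lower in delta than in beta libraries, with a median log2 fold change of 0.253. Hormone reads taking part of each library stay open as a cause, since the median was 0.059 with the reads of 7 hormone genes taken out of the totals. Gene length stays open too, since the median was 0.028 for the shortest quartile of genes and 0.507 for the longest. A true difference in RNA content between the cell types was not tested and could also add to the split.

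Other splits of the libraries were counted for the comparisons with at least 3 libraries per group. Of 56 splits of the alpha and beta libraries, 1, the real one, gave as many as 6864 called genes. The highest other gave 1. Of 60 splits by sex within cell types, 1, the real one, gave as many as 6 called genes. Here too the highest other gave 1. Other splits move the true difference into the spread within groups, so few calls in them were likely beforehand. The low counts of the other splits therefore say nothing about chance, and only the rank of the real split bears on it. So few splits can show no share under 1 in 56 or 1 in 60. The labels also do not say that each library is a separate pool, so chance is not excluded.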

How the results depend on the processing

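The alternatives voom on recovered reads, alpha share removed and hormone reads left out were chosen after seeing the data. The named genes were in large part chosen for large called differences, so few of their calls were likely to move. Counts over all genes, given below, moved more. Of 3398 comparisons of 151 gene results with their value under an alternative, 3371 kept the direction and the side of the threshold. Of the rest, 18 lost the call, 5 gained one and 4 turned direction, spread over 13 results. Those that turned were Gcg between delta and beta cells (-10.256 with the alpha share removed, by construction), and under quantile normalization Iapp between delta and beta cells (0.096) and Ppy (-0.169) and Pyy (-0.034) between delta and alpha cells, where the cause was not tested. Genes lower in delta than in beta cells numbered 2780 with median-ratio scaling and 2798 with hormone reads left out, and quantile normalization gave 2852 higher and 3200 lower. Between delta and alpha cells the counts were 1919 and 1360 with median-ratio scaling, 1963 and 2040 with quantile normalization, and 1872 and 1409 with hormone reads left out. With a mean RPKM of at least 3, and so fewer genes tested, 459 were lower in delta than in alpha cells, and the enriched sets held 332 (delta) and 133 (alpha) genes; quantile normalization gave 375 in the delta set. With the alpha share removed, the delta to beta counts were 3780 and 2194. Leaving out each replicate in turn gave 2335 to 4987 genes higher and 938 to 1677 lower in delta than in beta cells, the lowest of both without delta replicate 1. It gave 1838 (without alpha replicate 3) to 3222 genes higher in alpha than in beta cells. Between delta and alpha cells it gave 2181 (without delta replicate 1) to 4595 higher and 481 (without delta replicate 2) to 787 lower. The interaction of cell type and sex gave 1 gene with median-ratio scaling and 0 to 5 (without alpha replicate 2) when replicates were left out. Without alpha replicate 3 no female alpha library is left, and the interaction could not be fitted. With the beta libraries split, the genes higher in both comparisons numbered 1078 at the lowest and 1531 at the median, and those lower in both 861 at the lowest. Neighbouring title numbers were tried as a block, which gave 6138 higher and 1956 lower genes between delta and beta cells and called Pdx1 as lower in delta cells (adjusted p = 0.027). The consensus correlation within these blocks was 0.432. The deviations from the group means of such libraries correlated at 0.464, 0.372, 0.269 and 0.001, and not every library correlated best with its own neighbour, so they were not treated as paired. The delta libraries deviate from their mean as mirror images, and sex was left in the deviations. This check therefore cannot rule pairing out. At the recovered depth 1 RPKM is 16.7 to 26.7 reads per kb, so values far below 1 RPKM rest on few reads.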

Other observations

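The list tests in this part were planned, while the single genes given library by library were chosen after their values were seen. Genes of the cell cycle were lower in alpha than in beta cells in 3 of 7 tested cases, also adjusted over the list alone. Mcm2 and Mcm5, parts of the replicative helicase, stood at 5.05 and 1.20 RPKM in alpha, 10.9 and 3.32 in beta and 8.65 and 2.70 in delta libraries, and Ccnd1, cyclin D1, at 33.3, 56.6 and 75.6 RPKM. Between delta and beta cells 1 of the 7 was higher as deposited, but 0 adjusted over the list alone, and 2 were lower under median-ratio scaling. Between delta and alpha cells 4 were higher, also adjusted over the list alone, and 1 under median-ratio scaling.

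Ductal markers were higher in delta cells than in beta cells in 4 of 10 cases and lower in 1, and than in alpha cells in 6 and 1, in both comparisons also adjusted over the list alone. Tspan8, a tetraspanin, stood at 289 RPKM in delta, 15.2 in beta and 23.7 in alpha libraries, and Sox9, a factor of duct cells, at 3.51, 0.107 and 0.152 RPKM. Few markers of other cell types passed the filter. Of 3 endothelial markers 1 was higher in delta than in beta cells and than in alpha cells, and 0 were called between alpha and beta cells (limma). Of 3 Schwann cell markers 2 were higher in delta than in beta cells, and 1 each in the other comparisons, higher in alpha than in beta and in delta than in alpha cells. Of 2 mesenchymal markers 1 was higher in delta than in beta cells (0 under median-ratio scaling) and 1 in alpha than in beta cells. Between delta and alpha cells 1 of the 2 was lower, Col1a2, a collagen chain at 0.445 RPKM in delta, 0.101 in beta and 2.17 in alpha libraries. The mesenchymal list as a whole had a camera adjusted p = 0.0442, and adjusted p = 0.345 with an estimated correlation. Bhlha15, a factor of acinar cells also known as Mist1, stood at 16.4 RPKM in delta, 19.7 in beta and 5.92 in alpha libraries and was the single acinar marker called, lower in alpha than in beta cells and higher in delta than in alpha cells, the latter not called under median-ratio scaling (adjusted p = 0.0519). Ribosomal protein genes had 10 higher and 9 lower of 76 in alpha against beta cells, 4 and 5 adjusted over the list alone, and 12 and 4 under median-ratio scaling. Sex-linked genes had 1 higher of 9 in delta against beta cells, also adjusted over the list alone, 1 in alpha against beta cells (0 adjusted over the list alone), and 0 called between delta and alpha cells (limma).

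Acinar transcripts varied from library to library, with Ctrb1, a chymotrypsinogen, at 70.8 to 3440 RPKM in beta and 28.1 to 962 in alpha libraries. The nuclear RNA Malat1 stood at 327 and 217 RPKM in delta, 18.8, 22.1, 99.1, 41.5 and 192 in beta, and 289, 422 and 481 in alpha libraries. Rn45s, the ribosomal RNA precursor, stood at 7440 RPKM in alpha replicate 1 and at 534 to 1370 in the others.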
